A study of Mus musculus with 28 samples.

How the data were processed

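Total RNA from the liver of 28 male mice was hybridised by the authors to Agilent whole mouse genome arrays with 62976 spots, labelled in 1 colour, with 1 array per animal. The animals form 6 groups: CD-1 mice fed 0 or 1500 ppm phenobarbital for 7 days (n = 4 each), hCAR/hPXR mice fed 0 or 1000 ppm for 7 days (n = 7 each), and C3H mice fed 0 or 500 ppm for 27 weeks after 90 mg/kg diethylnitrosamine (n = 3 each), per the labels. The groups, the comparisons, the tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined.

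Per the file headers, the scanner files hold intensity values made by Agilent Feature Extraction 10.7.3.1: the processed signal of each spot, which is background-subtracted and detrended within its array and not normalized between arrays, and the median brightness of the spot and of its local background. The deposited value table of the series holds log2 values, which the authors made by subtracting the 75th percentile of each array. Of its 55821 entries 55681 matched probes of the scanner files, and every array's column was its log2 processed signal minus a constant, with constants between -0.0014 and 0.2536 away from the percentile used here.

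For the values used here, spots marked as outliers by the scanner software (109 to 430 per array) were left out, no spot was saturated, replicate spots of a probe were averaged on the log2 scale, and the 75th percentile of the 55681 non-control probes was subtracted from the log2 processed signal of each array. No array was left out. The files hold no gene symbols, so each probe's RefSeq accession was matched, without its version, to the gene names of the mouse annotation GRCm38.p6. This named 26582 probes with 20145 symbols, and 29099 probes stayed without a symbol. Each gene, or transcript where no symbol was found, was represented by the probe with the highest mean over all 28 arrays, which gave 37208 genes and transcripts, 9668 of them with several probes. Among genes with several tested probes of which 1 or more was called, 16 of 961 in CD-1, 229 of 3133 in hCAR/hPXR and 8 of 848 in C3H mice had probes called in opposite directions.

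A gene was tested in a comparison when it was well above background, by the scanner software's own mark, on every array of 1 or more of its groups. Phenobarbital was compared with control within each strain by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated t tests, 6, 12 and 4 residual degrees of freedom in CD-1, hCAR/hPXR and C3H mice), with p-values adjusted by Benjamini and Hochberg over all tested genes and a threshold of 0.05. Changes of at least 2-fold were counted as well. The difference of the phenobarbital effect between each pair of strains was tested as an interaction in 1 limma fit of all 28 arrays. Where no array of a group was well above background, the fold is a lower bound, for which that group's values were raised to the lowest value on each array that was marked well above background. The mouse receptor genes Nr1i3 and Nr1i2 were compared between control groups by exact two-sided permutation tests.

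The gene lists numbered 31 and held 521 genes, of which 506 were on the array. They were CAR- and PXR-responsive P450 genes, conjugation and other drug-metabolism genes, hepatobiliary transporters, haem synthesis and P450 reduction, cell cycle, bile acid synthesis, cholesterol synthesis and uptake, fatty acid synthesis, fatty acid oxidation and PPARA targets, gluconeogenesis and amino acid breakdown, NRF2 targets, pericentral genes and beta-catenin targets, periportal genes, fetal liver and liver tumour markers, p53 targets, ER stress and ATF4 targets, acute phase proteins, interferon-stimulated genes, male-biased and female-biased liver genes, circadian clock, immediate-early and heat-shock genes, hepatocyte secreted proteins, Kupffer cells and macrophages, lymphocytes, neutrophils, endothelial cells, stellate cells and fibroblasts, bile duct cells, red blood cells and exocrine pancreas. Each was tested by limma's camera with a preset correlation between genes of 0.01, again with an estimated correlation, and by fry, with at least 3 tested members, and adjusted over the lists. Counts of members past the threshold are over all genes and, separately, adjusted over the list alone.

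The genes named in each comparison follow a rule with 4 parts. The first names 14 genes whatever their values: Nr1i3, Nr1i2, Cyp2b10, Cyp2c55, Cyp3a11, Cyp1a2, Por, Alas1, Cyp7a1, Ccnd1, Mki67, Gadd45b, Afp and Glul. The second takes the 8 largest rises and the 8 largest falls among called genes with an assigned symbol (pseudogenes and provisional names left out), well above background on every array of both groups, whose groups do not overlap. The third takes the 3 largest lower bounds each way, and the fourth up to 4 called members of a list with the smallest adjusted p. For differences between strains the rule takes the 5 largest each way among genes with a symbol that are well above background on every array of all 4 groups, and the 14 genes. Some genes that the rule names are not reported here.

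The arrays lay on 5 slides and were scanned on 3 days, a different day for each strain. All CD-1 controls shared 1 slide and all CD-1 phenobarbital animals another. The hCAR/hPXR controls shared a slide with phenobarbital animal 1, and phenobarbital animals 2 to 7 lay on another. All C3H arrays shared 1 slide. A slide block could therefore be fitted for hCAR/hPXR mice alone, where it rests on phenobarbital animal 1, assumed to vary like the other animals.

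Alternatives tried 1 at a time were quantile normalization, scaling to the median of detected probes, the authors' value table, no filter on dim probes, detection in both groups, eBayes with trend and robust, all 6 groups in 1 fit, each probe on its own, the mean of a gene's probes, array weights, a slide block, the replicate number as a block, and leaving out each animal in turn. A background correction by normexp with an offset of 50 followed by quantile normalization had been planned on mean spot signals. The files hold no such column, so it was run on median spot signals. This, the arrays of 1 slide, detection on all 28 arrays, genes with a symbol alone, slide-blocked list tests, exchanges of animals between groups and leave-one-out for named genes were chosen after seeing the data.

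Other splits of the animals were counted for each result, all 35 for CD-1 and all 10 for C3H mice, and 100 drawn with a fixed seed elsewhere. The procedure was tested on simulated data with the observed spread and 50 planted changes per size. A log2 change of 2 was recovered in 50% of cases in CD-1, 94% in hCAR/hPXR and 70% in C3H mice, and of 1 in 2%, 90% and 34%. False calls were 1.37%, 5.23% and 3.00% of calls, for simulated data alone. Figures used Python 3.11.15 and matplotlib 3.10.9.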

Results

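Liver RNA of 28 male mice was measured on 1-colour Agilent mouse arrays, 1 array per animal, in 3 separate feeding experiments with phenobarbital, a barbiturate that induces drug-metabolising enzymes through the nuclear receptor CAR. CD-1 mice, an outbred stock, received 0 or 1500 ppm in the diet for 7 days (n = 4 per group). hCAR/hPXR mice, in which the mouse receptors CAR and PXR are replaced by the human ones, received 0 or 1000 ppm for 7 days (n = 7 per group). C3H/HeNCrlCrlj mice, called C3H below, received 0 or 500 ppm for 27 weeks after a single intraperitoneal dose of 90 mg/kg diethylnitrosamine, a liver carcinogen given to both of their groups (n = 3 per group). The labels say liver and do not say whether the C3H samples were tumour or surrounding tissue.

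The share of probes well above background lay between 46.4% and 70.6% on the CD-1 arrays, between 47.8% and 59.4% on the hCAR/hPXR arrays and between 42.6% and 47.3% on the C3H arrays. The brightest probes of the CD-1 arrays were dimmer, with a 99th percentile of the processed signal of 4019 to 6490 against 30159 to 48010 in hCAR/hPXR mice and 22576 to 31394 in C3H mice. The median CV of replicate spots was out of the scanner software's range on all CD-1 arrays (11.0 to 13.1% in controls, 17.7 to 21.2% in phenobarbital animals) and on 3 of 14 hCAR/hPXR arrays, and the negative controls were out of range on all hCAR/hPXR arrays. Values below are log2 changes, phenobarbital minus control, with the standard error of the fit. Each phenobarbital animal lay on the stated side of each control animal for every gene described as risen or fallen, except where overlap is stated. Rankings of single genes cover genes with a symbol, pseudogenes and provisional names left out, that were detected on every array of the groups compared, within a strain with groups that did not overlap. "At least" marks a fold against a group in which no array was well above background. Chromosomes are those of mouse build GRCm38.p6.

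The first comparison, 7 days in CD-1 mice with mouse receptors, cannot tell phenobarbital from slide. Cyp2b10, the cytochrome P450 gene used as the standard marker of CAR activation, on chromosome 7, rose 101-fold (6.66 ± 0.47, n = 4 per group, limma adjusted p = 1.88e-05). Cyp2c55, a P450 gene also responsive to CAR and PXR, on chromosome 19, rose at least 29.7-fold (adjusted p = 1.88e-05). Por, the reductase that supplies P450 enzymes with electrons, rose 4.15-fold (2.05 ± 0.40, adjusted p = 0.00870), and Gadd45b, a stress gene induced through CAR, rose 4.18-fold (2.06 ± 0.32, adjusted p = 0.00196). Alas1, the first enzyme of haem synthesis, rose by 1.65 ± 0.40 (adjusted p = 0.0252) on its main probe, while its second probe gave 0.14. Cyp3a11, the main mouse target of PXR, gave 0.34 ± 0.40 (adjusted p = 0.601), Cyp1a2 gave -0.12 ± 0.34 (adjusted p = 0.842) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, gave 0.20 ± 0.65 (adjusted p = 0.861). The receptor genes Nr1i3, for CAR (-0.44 ± 0.26, adjusted p = 0.287, second probe -1.25), and Nr1i2, for PXR (-0.08 ± 0.27, adjusted p = 0.873), did not pass, and Ccnd1 and Afp were not well above background on all arrays of a CD-1 group and were not tested.

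Among 19 tested P450 genes listed as responsive to CAR and PXR, 12 rose, and 15 rose when adjusted over the list alone. They included Cyp2b9 (19.6-fold, well above background on 3 of 4 control arrays), Cyp2b13 (9.05-fold, on 2 of 4), Cyp2c54 (6.64-fold) and Cyp2a4 (6.06-fold). The list's median was 2.13 (camera adjusted p = 1.53e-14, adjusted p = 0.318 with an estimated correlation). Below, counts of called members were the same when adjusted over the list alone unless other counts follow, and the second of 2 adjusted p of a list is with an estimated correlation. Of 24 conjugation and other drug-metabolism genes, 13 rose, and 15 when adjusted over the list alone (median 1.22, adjusted p = 4.09e-10 and 0.612). The glutathione transferases Gstm3, Gsta1 and Gsta2 rose 16.5-fold, 13.9-fold and 6.85-fold, and the aldo-keto reductase Akr1b7 rose at least 6.79-fold. Genes that are higher in female than in male mouse liver rose in 6 of 10 cases, and in 6 when adjusted over the list alone. Their median was 1.78 (adjusted p = 1.19e-06 and 0.0454). Besides Cyp2b9, Cyp2b13 and Cyp2a4, this group holds the sulfotransferase Sult3a1, which rose at least 4.53-fold.

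The largest rise in CD-1 mice among named genes detected on every array was that of S100a8, which codes for a calcium-binding protein abundant in neutrophils, at 102-fold (6.67 ± 0.29, adjusted p = 1.88e-07). It was the 1 of 8 neutrophil genes that rose (list median 0.49, adjusted p = 0.0493 and 0.593). Among 20 acute phase proteins of the liver, 2 rose and 1 fell, with the same counts when adjusted over the list alone (median 0.23, adjusted p = 0.119). Orm3 rose 6.14-fold and Lcn2 rose by 2.06 ± 0.51, with the Lcn2 values of the groups overlapping. Prom1, a surface marker of progenitor cells, rose at least 16.4-fold on its main probe, while its second probe, well above background on 3 of 4 control arrays, gave 0.41, and Meig1, a gene of meiosis, rose at least 14.9-fold. Of 9 fetal liver and liver tumour markers 2 rose, Prom1 and Lcn2, and 2 rose and 1 fell when adjusted over the list alone (median 0.70, adjusted p = 0.0222 and 0.593).

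Cell cycle genes passed in 3 of 15 cases in CD-1 mice (median 0.47, adjusted p = 0.0165 and 0.612). Cdc20, an activator of the complex that starts anaphase, rose at least 3.68-fold, Birc5, needed for chromosome segregation, rose 3.84-fold (well above background on 3 of 4 control arrays, other probes -0.01 and 0.78), and Kif11, a motor of the mitotic spindle, rose 3.14-fold (on 1 of 4). Mki67, the common marker of dividing cells, gave 0.51 ± 0.34 (adjusted p = 0.345). The export pump Abcc4 rose at least 2.02-fold and the uptake carrier Slco1a1 fell 3.27-fold. In all, 1 of 16 hepatobiliary transporters rose and 2 fell, and 1 rose and 4 fell when adjusted over the list alone (median -0.48, adjusted p = 0.0905). Of 13 genes of haem synthesis and P450 reduction 2 rose and 2 fell, and 3 rose and 3 fell when adjusted over the list alone (median -0.52, adjusted p = 0.437).

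Glul, the glutamine synthetase of the hepatocytes around the central vein, fell 3.67-fold in CD-1 mice (-1.87 ± 0.37, adjusted p = 0.00874). Slc1a2, a glutamate carrier of the same cells, fell 4.07-fold, and Oat, an enzyme of ornithine metabolism, fell 2.41-fold. These were the 3 of 16 pericentral genes that fell (median -0.42, adjusted p = 0.0297 and 0.612). Among 14 periportal genes 1 fell, Etnppl, at 4.22-fold, and 9 fell when adjusted over the list alone (median -0.83, adjusted p = 0.00300 and 0.612). G6pc, the last enzyme of glucose release, fell 3.32-fold and Tat, a tyrosine-degrading enzyme, fell 2.76-fold with overlapping groups. They were 2 of the 3 of 14 genes of gluconeogenesis and amino acid breakdown that fell, and 9 fell when adjusted over the list alone (median -0.80, adjusted p = 9.98e-05 and 0.612).

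Alb, serum albumin, fell 3.92-fold in CD-1 mice and Apoa1, an apolipoprotein of high-density lipoprotein, fell 2.49-fold. These were the 2 of 14 hepatocyte secreted proteins that fell (median -0.55, adjusted p = 0.0131 and 0.649). Of 19 genes of fatty acid oxidation and PPARA targets 1 fell, and 13 fell when adjusted over the list alone (median -1.01, adjusted p = 0.000240 and 0.612). Of 13 male-biased liver genes 3 fell, Slco1a1, Cyp7b1 (2.75-fold) and Susd4 (-1.63), and 5 fell when adjusted over the list alone (median -0.80, adjusted p = 0.00265 and 0.612). The largest fall was that of Spats2l, 16.0-fold (SE 0.27 on the log2 scale, adjusted p = 1.88e-05). Tmem130 (10.4-fold), Dppa4 (3.37 on the log2 scale on its main probe, while its other probes, each not well above background on every array, gave -0.22 and 1.54), Mdh1b (8.19-fold) and Nog, an antagonist of bone morphogenetic proteins (7.68-fold), followed. Esyt3 (7.61-fold), Gml2 (7.46-fold) and Rdh16f2 (7.10-fold) fell as well. The embryonic globin Hbb-bh1 fell at least 8.76-fold, the olfactory receptor gene Olfr1316 at least 7.17-fold and Sapcd2 at least 6.60-fold.

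Across 23832 genes and transcripts tested in CD-1 mice, 1901 (7.98%) changed, 439 higher and 1462 lower, and 1833 of them changed at least 2-fold. Higher calls were 23.1% of all, 33.7% with quantile normalization and 39.5% with normexp on median signals followed by quantile normalization. The groups did not overlap for 4435 genes, where chance gives 2.86%. Leaving out control animal 3 gave 910 genes, and leaving out phenobarbital animals 1, 2 or 4 gave 1168, 942 or 1082. With 1 animal left out, Alas1, Lcn2, Oat, G6pc, Tat, Apoa1, Susd4, Birc5 and Abcc4 each lost their call at least once, while 36 of the 45 named calls were made whichever animal was left out. All control arrays lay on 1 slide and all phenobarbital arrays on another, so slide and treatment were not separable.

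**Figure D1:**
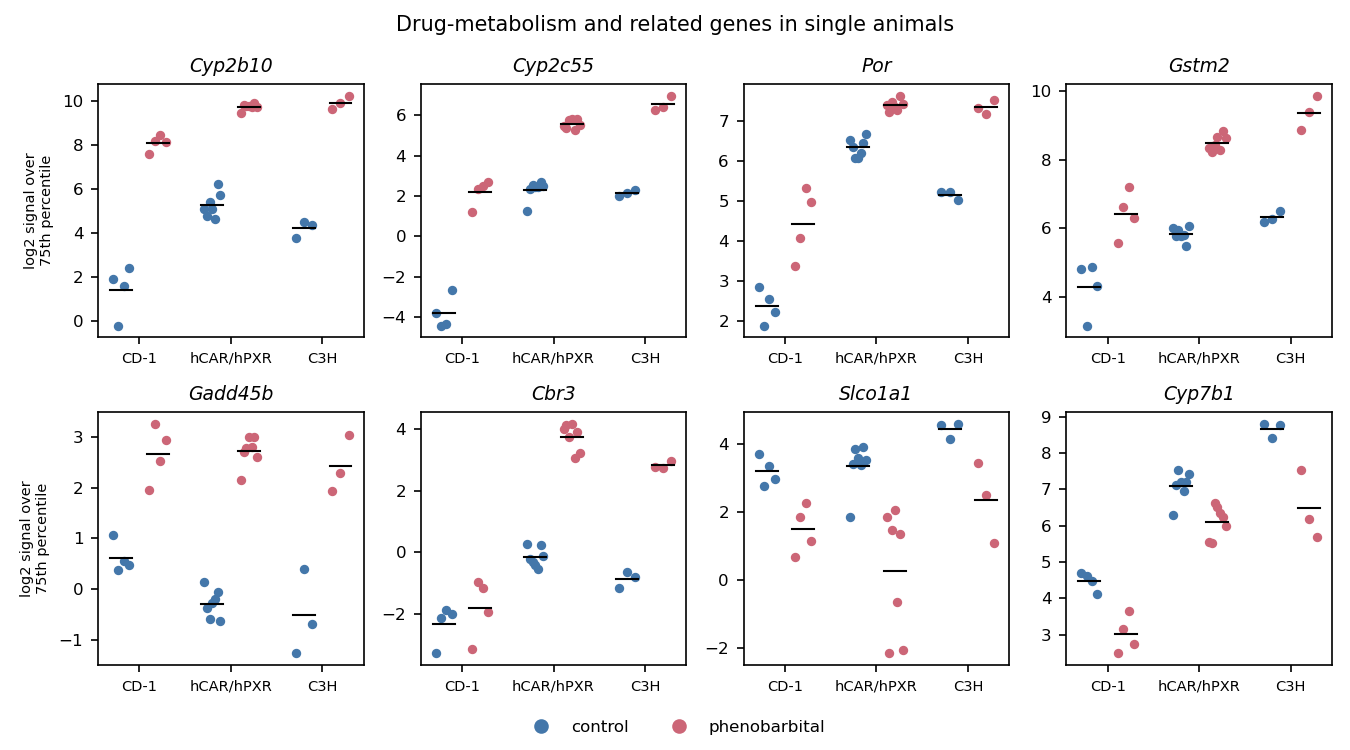
Per-animal values (log2, relative to each array's 75th percentile) of Cyp2b10, Cyp2c55, Por, Gstm2, Gadd45b, Cbr3, Slco1a1 and Cyp7b1 in control and phenobarbital animals of the 3 strains; points are animals and lines are group means. Cyp2b10 means rose by 6.66, 4.45 and 5.69 in CD-1, hCAR/hPXR and C3H mice.

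The second comparison set phenobarbital against control in mice carrying human CAR and PXR. Cyp2b10 rose 21.8-fold (4.45 ± 0.20, n = 7 per group, adjusted p = 2.62e-09), and the estimate with the slide as a block was 4.18. The arrays lay on 2 slides, the first with all controls and phenobarbital animal 1, the second with phenobarbital animals 2 to 7. Blocked values therefore rest on phenobarbital animal 1 against the controls, are the same as those from the arrays of the first slide alone, and assume that this animal varies like the others. Their standard errors are wider (0.41 against 0.20 for Cyp2b10), so a call lost with the block does not by itself show a difference between slides. Cyp2b9 rose 29.1-fold (blocked 4.71) and Cyp2c55 rose 9.58-fold (3.26 ± 0.19, blocked 3.15). Por rose 2.08-fold (1.06 ± 0.10, adjusted p = 4.60e-06, blocked 1.05) and Gadd45b rose 8.08-fold (3.01 ± 0.15, adjusted p = 5.72e-09, blocked 2.44). Cyp1a2, a P450 gene of the pericentral hepatocytes, rose 2.01-fold (SE 0.19 on the log2 scale, adjusted p = 0.000460), with a blocked value of 0.70 that did not pass (adjusted p = 0.405). Cyp3a11 gave 0.14 ± 0.08 (adjusted p = 0.162, blocked -0.02, second probe 1.20), Alas1 gave 0.25 ± 0.18 (adjusted p = 0.255, blocked 0.22) and Cyp7a1 gave 0.59 ± 0.38 (adjusted p = 0.199, blocked 0.69).

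Of 19 CAR- and PXR-responsive P450 genes 16 rose in hCAR/hPXR mice, and 10 rose with the slide as a block. The list's median was 1.08 (adjusted p = 3.50e-09 and 0.195) and 0.87 with the block. Among 26 conjugation and other drug-metabolism genes 24 rose and 1 fell, and 12 rose with the block (median 0.98, blocked 0.99, adjusted p = 8.15e-11 and 0.195). Gstm2 rose 6.22-fold (2.64 ± 0.11, blocked 2.50), Gstm4 rose 5.58-fold (blocked 2.56), Gstt3 rose by 1.63 on the log2 scale (blocked 1.37) and Akr1b7 rose 23.9-fold (blocked 4.27). The sulfotransferases of the female liver were not well above background in any control animal and reached at least 283-fold for Sult2a2, 121-fold for Sult2a1, 32.9-fold for Sult2a4 and 30.2-fold for Sult3a1, and all 4 passed with the block.

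Female-biased genes rose in 7 of 12 cases and fell in 3 in hCAR/hPXR mice, and 5 rose with the slide as a block (median 1.17, blocked 1.40, adjusted p = 0.0225 and 0.278). Cyp2a4, a member of that group, rose 3.14-fold (blocked 1.39). Male-biased genes fell in 8 of 12 cases, and in 9 when adjusted over the list alone, while limma called 0 with the block (4 at unadjusted p under 0.05, median -0.54, blocked -0.76, adjusted p = 0.00350 and 0.570). Hsd3b5, a steroid dehydrogenase of male liver, fell 13.8-fold (-3.79 ± 0.93, blocked -1.80) and Slco1a1 fell 8.57-fold (SE 0.68 on the log2 scale, blocked -1.51). Cyp7b1, which hydroxylates oxysterols and sex steroids, fell 1.98-fold (blocked -1.55), and Nudt7 fell 1.68-fold (blocked -0.76). The groups overlapped for these 4 male-biased genes, and none of their blocked values passed.

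All 30 tested cell cycle genes rose in hCAR/hPXR mice, and 6 rose with the slide as a block (median 1.87, blocked 1.88, adjusted p = 3.61e-11 and 0.346). Mki67 rose 5.55-fold (2.47 ± 0.25, adjusted p = 5.72e-06, blocked 2.22), and Ccna2, the cyclin of S phase and G2, rose 5.53-fold (blocked 2.23). Birc5 rose 4.50-fold (blocked 2.04), Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, rose 4.49-fold (blocked 2.08) and Bub1, a kinase of the spindle checkpoint, rose at least 1.79-fold and passed with the block. Ccnd1, cyclin D1, rose by 0.53 ± 0.09 (adjusted p = 0.000200), a call lost with the block (0.53, adjusted p = 0.152). Of 14 p53 targets 9 rose and 1 fell, and 1 rose with the block (median 0.53, blocked 0.45, adjusted p = 0.0313 and 0.555). Among them Phlda3 rose 4.26-fold (blocked 1.88), Bbc3 rose 1.74-fold (blocked 0.63, not passing) and Ccng1 rose 1.56-fold (blocked 0.41, not passing).

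Cholesterol synthesis and uptake genes rose in 21 of 23 cases in hCAR/hPXR mice, while limma called 0 with the slide as a block (10 at unadjusted p under 0.05, median 0.52, blocked 0.53, adjusted p = 3.53e-05 and 0.546). The synthesis enzymes Lss, with overlapping groups, and Fdft1 rose 2.06-fold (blocked 0.87) and 1.88-fold (blocked 0.72). Targets of NRF2, the regulator of the response to electrophiles, rose in 13 of 19 cases, and in 6 with the block (median 0.68, blocked 0.71, adjusted p = 6.71e-05 and 0.243). The carbonyl reductases Cbr3 and Cbr1 rose 14.9-fold (3.90 ± 0.19, blocked 4.14) and 2.67-fold (blocked 1.19). Srxn1, sulfiredoxin, rose 2.49-fold (blocked 1.31), and Ugdh, which supplies glucuronic acid for conjugation, rose 2.01-fold (blocked 1.01). Of 17 hepatobiliary transporters 8 rose and 1 fell, and 2 rose with the block (median 0.49, blocked 0.19, adjusted p = 0.0225 and 0.570). The rises included Abcc4 (12.0-fold, blocked 3.93), Slco1a4 (2.78-fold, blocked 1.59) and Abcc3 (1.81-fold, blocked 0.60, not passing). Genes of haem synthesis and P450 reduction rose in 8 of 13 cases, and in 1, Por, with the block (median 0.34, blocked 0.22, adjusted p = 0.0155 and 0.430).

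Fetal liver and liver tumour markers rose in 9 of 15 cases in hCAR/hPXR mice, and in 2 with the slide as a block (median 0.86, blocked 0.69, adjusted p = 0.0126 and 0.463). Prom1 rose 99.6-fold (6.64 ± 0.25, adjusted p = 9.20e-10, blocked 5.77). Ly6d, a surface protein of early B cells and some epithelia, rose 17.3-fold (blocked 3.42, not passing), and Afp, alpha-fetoprotein, rose by 0.86 ± 0.16 (adjusted p = 0.000387, blocked 0.78, not passing). Meig1 rose 18.6-fold (blocked 4.16) and Krt31, a hair keratin, 15.5-fold (blocked 4.68). Of 20 acute phase proteins 12 rose, and 13 when adjusted over the list alone (median 0.58, adjusted p = 0.0249 and 0.900). With the block that list's median turned to -0.13 (adjusted p = 0.314) and limma called 0 members (1 at unadjusted p under 0.05), and Lcn2 (2.76 ± 0.84), Apcs (1.93 ± 0.55) and Saa1 (1.72 ± 0.53), whose groups overlapped, had blocked values of 0.83, 0.40 and 0.80 that did not pass.

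Glul, well above background on 6 of 7 phenobarbital arrays, gave -0.01 ± 0.11 (adjusted p = 0.948, blocked -0.41) in hCAR/hPXR mice. Of 17 pericentral genes 7 rose and 2 fell, while with the slide as a block limma called 0 higher and 1 lower, Slc1a2 (-0.82), of 7 at unadjusted p under 0.05 (median 0.09, blocked -0.17, adjusted p = 0.426). Among genes whose groups did not overlap, with a symbol and detected on every array, the largest falls were those of Duox1, which makes hydrogen peroxide, at 5.71-fold (-2.51 ± 0.23, blocked -1.21), Klhl32 at -2.46 (blocked -0.73), the vomeronasal receptor gene Vmn1r48 at 5.48-fold (blocked -1.0) and the crystallin gene Cryaa at 5.42-fold (blocked -0.82). Aatk fell 4.50-fold (blocked -1.84), Prnd 4.41-fold (blocked -0.89), Serpina3h 4.38-fold (blocked -1.11) and Vmn1r87 4.36-fold (blocked -0.83). Of these 8, Duox1, Vmn1r48, Aatk and Serpina3h passed with the block. Klf17, Epp13 and Ghrl fell at least 2.31-fold, 2.24-fold and 2.01-fold, calls lost with the block, though the fitted values of Klf17 and Ghrl stayed nearly as large. Nr1i3, the mouse gene for CAR, of which the array still measured a transcript, fell by 1.03 on the log2 scale (adjusted p = 1.78e-05) on its main probe, a call lost with the block (-0.67). Its second probe was not well above background in control animals. Nr1i2 was too dim in both groups to be tested.

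Of 20039 genes and transcripts tested in hCAR/hPXR mice, 11158 (55.7%) changed, 6249 higher and 4909 lower, and 2002 changed at least 2-fold, 408 higher and 1594 lower. Without a filter on dim probes 5415 were higher and 5719 lower, and with all 6 groups in 1 fit 3702 and 4093. With the slide as a block 438 changed, 240 higher and 198 lower, and 293 at least 2-fold, 174 higher and 119 lower. Of the 438, 372 were also called without the block, and the first slide alone gave 251, 207 of them shared. The groups did not overlap for 3963 genes, where chance gives 0.0583%. All 57 named calls were made whichever animal was left out.

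**Figure D2:**
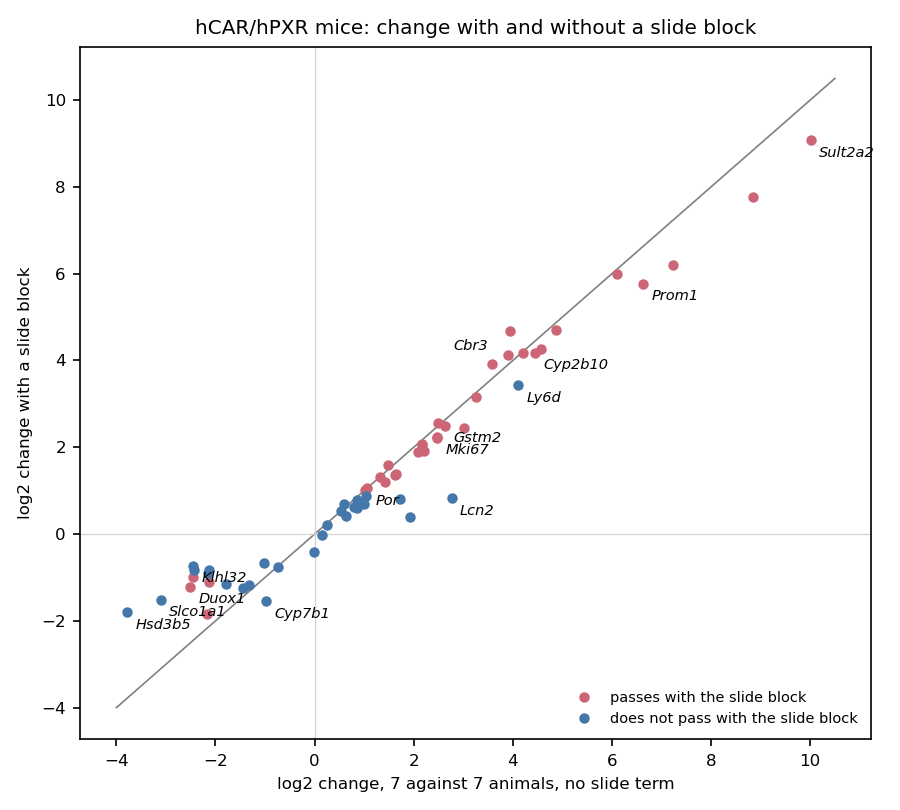
Log2 changes of the 61 named genes in hCAR/hPXR mice without (x axis) and with (y axis) the slide as a block; red points passed with the block, blue points did not. Cyp2b10 lies at 4.45 and 4.18, Duox1 at -2.51 and -1.21. Genes not well above background in a group, such as Sult2a2, are drawn at fitted values that are not measured differences.

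The third comparison concerns long feeding after a carcinogen, in C3H mice whose 6 arrays shared 1 slide. Cyp2b10 rose 51.7-fold (5.69 ± 0.24, n = 3 per group, adjusted p = 0.000326) and Cyp2c55 rose 21.2-fold (4.41 ± 0.20, adjusted p = 0.000328). Mki67 rose 20.8-fold (4.38 ± 0.42, adjusted p = 0.00312), and Glul, which fell in CD-1 mice, rose 8.78-fold (3.13 ± 0.29, adjusted p = 0.00266). Afp rose 13.3-fold (3.73 ± 0.87, adjusted p = 0.0367). Por rose 4.55-fold (2.19 ± 0.14, adjusted p = 0.00109), Cyp1a2 rose 3.98-fold (1.99 ± 0.20, adjusted p = 0.00365) and Gadd45b rose 7.71-fold (2.95 ± 0.47, adjusted p = 0.0149). Cyp3a11 gave -0.24 ± 0.14 (adjusted p = 0.243), Alas1 gave 0.86 ± 0.64 (adjusted p = 0.372) and Cyp7a1 gave 0.54 ± 0.25 (adjusted p = 0.175). The receptor genes Nr1i3 (-0.28 ± 0.19, adjusted p = 0.328) and Nr1i2 (0.58 ± 0.16, adjusted p = 0.0576), did not pass.

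Among 19 CAR- and PXR-responsive P450 genes 12 rose and 1 fell in C3H mice, and 13 rose and 1 fell when adjusted over the list alone (median 1.12, adjusted p = 4.46e-09 and 0.179). Cyp2c65 rose at least 64.0-fold, Cyp2b13 84.9-fold, Cyp2b9 by 5.91 on the log2 scale, Cyp2c66 57.7-fold and Cyp2a4 3.82-fold. Of 26 conjugation and other drug-metabolism genes 14 rose and 1 fell, and 16 rose and 1 fell when adjusted over the list alone (median 0.91, adjusted p = 3.00e-09 and 0.320). Akr1b7, well above background on 1 of 3 control arrays, rose 87.9-fold, Gstm2 8.22-fold and Gstm3 4.57-fold. NRF2 targets rose in 7 of 19 cases and 1 fell, and 9 rose and 1 fell when adjusted over the list alone (median 0.43, adjusted p = 0.000235 and 0.474). Cbr3 rose 12.9-fold and the quinone reductase Nqo1 6.46-fold. Of 18 transporters 5 rose and 4 fell, and 8 rose and 4 fell when adjusted over the list alone (median 0.11, adjusted p = 0.0392 and 0.474), with Abcc4 up 101-fold and the organic anion carrier Slc22a7 down 7.36-fold. Genes of haem synthesis and P450 reduction rose in 3 of 13 cases (median 0.21, adjusted p = 0.00847 and 0.474).

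Cell cycle genes rose in 30 of 32 cases in C3H mice, and in 31 when adjusted over the list alone (median 3.67, adjusted p = 1.32e-25 and 0.409). Cdc20 rose 37.0-fold (5.21 ± 0.38, adjusted p = 0.00150), Prc1, a protein of the spindle midzone, 29.4-fold, Birc5 26.3-fold, Ccna2 25.7-fold and Ccnd1 5.11-fold, with Prc1 and Ccna2 well above background on 1 of 3 control arrays. Pericentral genes and beta-catenin targets rose in 15 of 19 cases, and in 18 when adjusted over the list alone (median 2.60, adjusted p = 2.90e-14 and 0.409). Nkd1, a feedback inhibitor of Wnt signalling, rose 27.1-fold (second probe 1.66, well above background on 1 of 3 control arrays), Rhbg, an ammonium transporter of pericentral hepatocytes, rose 13.1-fold, and Axin2, another Wnt feedback gene, rose at least 3.55-fold. Periportal genes fell in 3 of 15 cases and in 13 when adjusted over the list alone (median -2.84, adjusted p = 0.000200 and 0.484). The 3 were Sox9, a transcription factor of bile duct cells (at least 4.56-fold), Igfals (2.01-fold) and the lysosomal protease Ctsc (1.90-fold).

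Fetal liver and liver tumour markers rose in 8 of 17 cases in C3H mice, and in 12 when adjusted over the list alone (median 2.09, adjusted p = 8.24e-07 and 0.409). Prom1 rose 23.6-fold, and Dlk1 and Meg3, neighbouring imprinted genes of chromosome 12 active in fetal liver, rose 23.5-fold and 13.7-fold. Ly6d had the largest rise, at 373-fold (8.54 ± 0.95, adjusted p = 0.00507). The acylglycerol acyltransferase gene Mogat2 rose 57.6-fold and Calml4 rose 45.8-fold, while Acsm4 and Gipc2 rose at least 121-fold and 58.3-fold. Immediate-early and heat-shock genes rose in 8 of 14 cases, and in 10 when adjusted over the list alone (median 1.62, adjusted p = 6.67e-08 and 0.409). Fos rose at least 35.9-fold, Atf3 40.9-fold and Jun 8.56-fold. Of 13 p53 targets 4 rose, and 5 when adjusted over the list alone (median 0.48, adjusted p = 0.000229 and 0.474), among them Btg2, an inhibitor of proliferation, at 7.82-fold and Gdf15, a stress cytokine, at 4.08-fold. Ddit3 and Trib3, targets of the stress factor ATF4, rose 5.33-fold and 3.90-fold, and Usp18, an interferon-stimulated gene, rose 3.93-fold.

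Genes of glucose release and amino acid breakdown fell in 5 of 14 cases in C3H mice, and in 9 when adjusted over the list alone (median -1.36, adjusted p = 0.00454 and 0.474). G6pc fell 6.67-fold (-2.74 ± 0.44, adjusted p = 0.0150) and Tat fell 2.79-fold. Male-biased genes fell in 5 of 13 cases, and in 7 when adjusted over the list alone (median -1.38, adjusted p = 0.000485 and 0.474). Elovl3, a fatty acid elongase, fell 6.43-fold, Hsd3b5 5.49-fold, Cyp7b1 4.55-fold and Serpina3k 2.56-fold. Female-biased genes rose in 5 of 10 cases, and 6 rose and 1 fell when adjusted over the list alone (median 1.43, adjusted p = 0.00307 and 0.409). Hepatocyte secreted proteins fell in 7 of 14 cases, and in 13 when adjusted over the list alone (median -0.57, adjusted p = 6.10e-05 and 0.474), with Alb down 1.69-fold and Fgb, fibrinogen beta, down 2.05-fold. Bile acid synthesis genes fell in 4 of 12 cases, Cyp7b1 among them, and in 6 when adjusted over the list alone (median -0.38, adjusted p = 0.150). Among genes with a symbol, detected on every array, whose groups did not overlap, the largest falls were those of Enho, which codes for the secreted peptide adropin (13.2-fold, -3.73 ± 0.91), and Rdh16f2 (10.6-fold). Ripply2 fell 6.65-fold, Rnase2a 5.97-fold and Dpy19l3 5.88-fold. Lag3, an inhibitory receptor of T cells, fell at least 8.91-fold and Sgsm1 at least 4.75-fold.

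**Figure D3:**
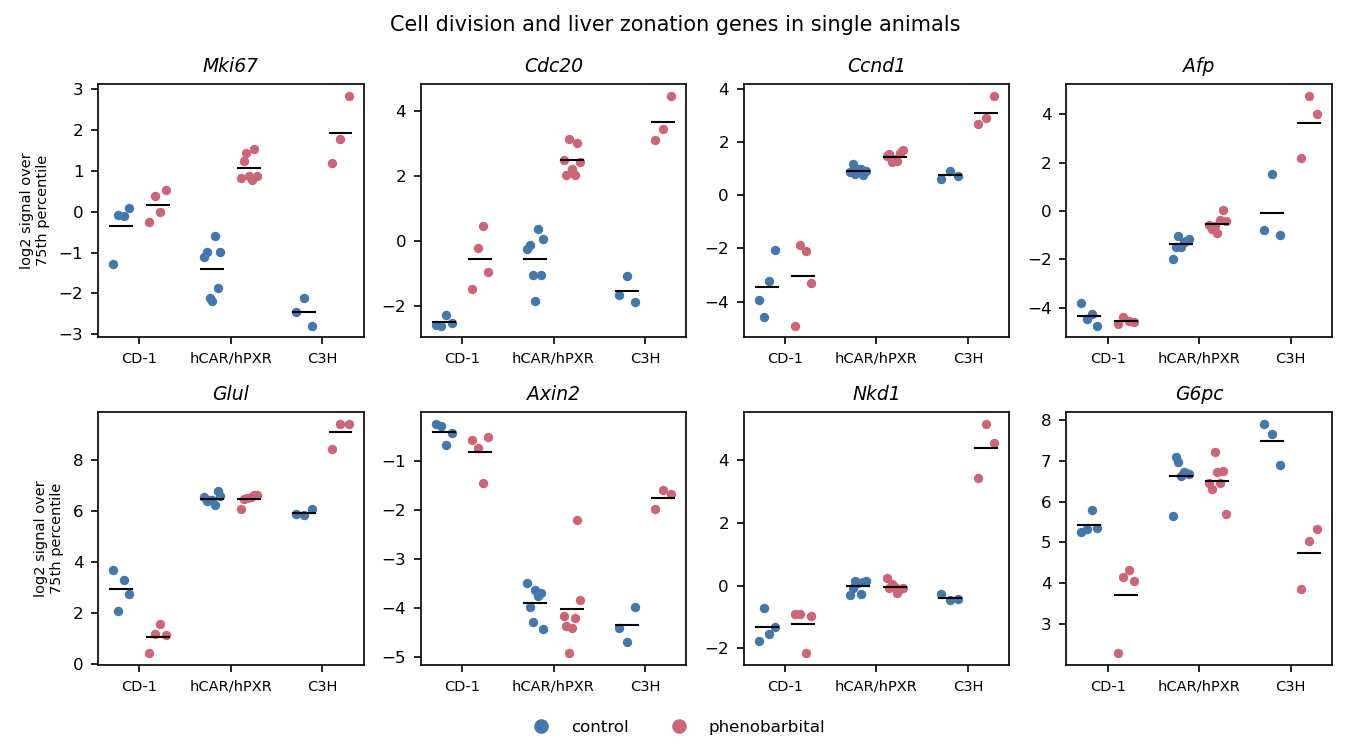
Per-animal values (log2, relative to each array's 75th percentile) of Mki67, Cdc20, Ccnd1, Afp, Glul, Axin2, Nkd1 and G6pc in control and phenobarbital animals of the 3 strains; points are animals and lines are group means. The Glul means differ by -1.87 in CD-1, -0.01 in hCAR/hPXR and 3.13 in C3H mice.

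Of 18273 genes and transcripts tested in C3H mice, 2913 (15.9%) changed, 1290 higher and 1623 lower, and 1448 changed at least 2-fold, 866 higher and 582 lower. Neither direction was stable. Higher calls were 44.3% of all, but 50.3% with the authors' values, 53.6% with the replicate number as a block, 55.6% with quantile normalization, 72.2% without a filter on dim probes, and 38.7% to 74.8% with 1 animal left out. Among changes of at least 2-fold 961 were higher and 986 lower with all 6 groups in 1 fit, 1064 and 1262 with array weights, and 1182 and 1478 without phenobarbital animal 1. The groups did not overlap for 7742 genes, where chance gives 10%. Leaving out control animals 1, 2 or 3 gave 622, 947 or 629 genes, and leaving out phenobarbital animals 1, 2 or 3 gave 5547, 642 or 1236. Of the 62 named calls 42 were made whichever animal was left out, and those of Gadd45b, Afp, Cyp2b13, Enho, Rdh16f2, Slc22a7, G6pc, Ripply2, Dpy19l3, Sgsm1, Sox9, Gdf15, Hsd3b5, Cyp7b1, Serpina3k, Alb, Fgb, Tat, Ctsc and Igfals were lost at least once.

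Of the 48 list calls in the 3 strains (16 in CD-1, 15 in hCAR/hPXR and 17 in C3H mice), the 1 that held with an estimated correlation was that of female-biased genes in CD-1 mice.

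**Figure D4:**
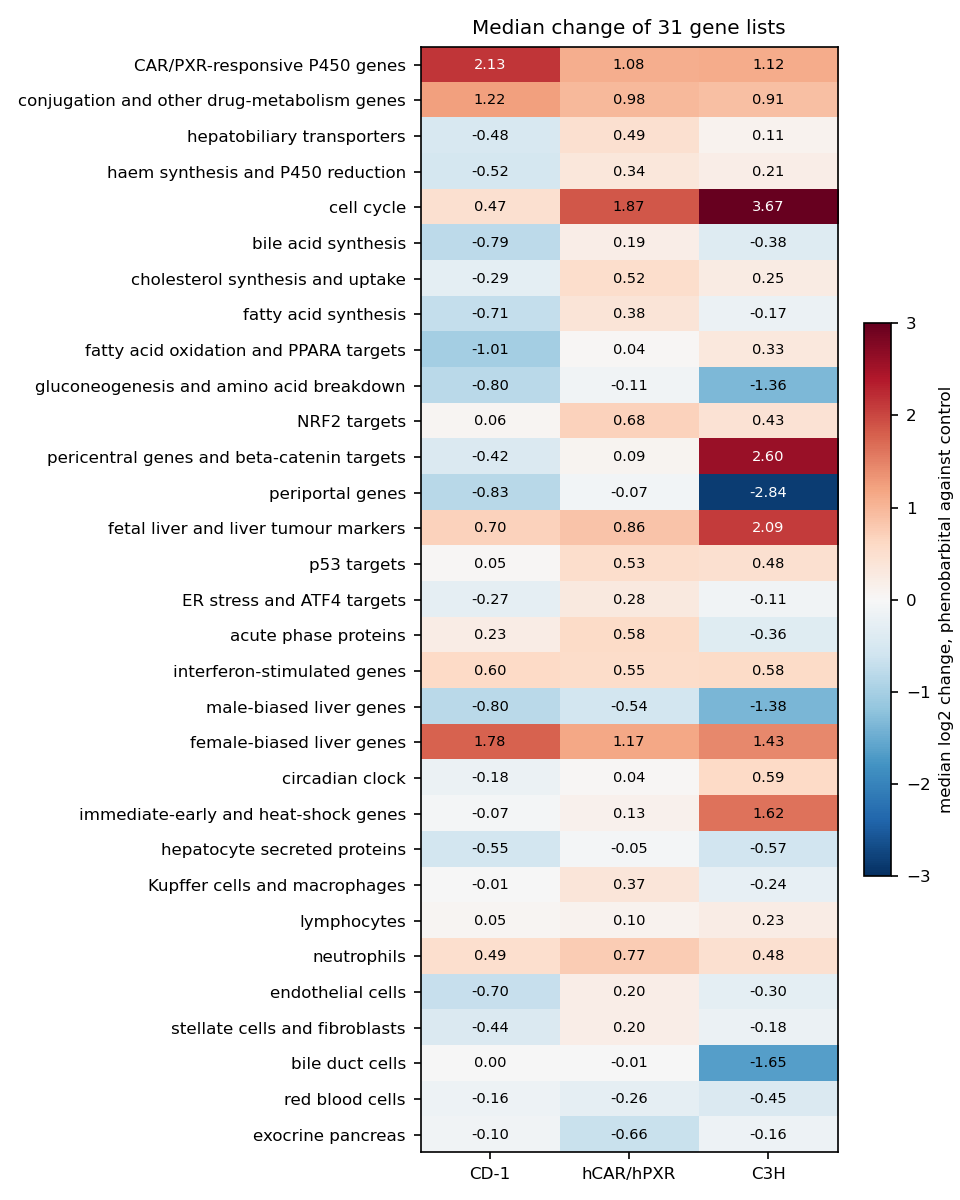
Median log2 change of each of the 31 gene lists in each strain, as colour and printed value; the colour scale ends at -3 and 3. The cell cycle list reads 0.47, 1.87 and 3.67 in CD-1, hCAR/hPXR and C3H mice, and the pericentral list -0.42, 0.09 and 2.60.

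Whether the effect of phenobarbital itself differed between strains was tested in 1 fit of all 28 arrays. Strain, dose, duration, diethylnitrosamine, slide and scan day differed together, so these differences are between experiments. The effect, with its sign, was more positive in hCAR/hPXR than in CD-1 mice for 4904 genes and more negative for 2620, of 27103 tested. Of these 7524 genes, 5989 had effects of opposite sign in the strains compared. Scaling to the median of detected probes turned the counts to 2796 more positive and 4812 more negative. Cyp2b10 rose less in hCAR/hPXR than in CD-1 mice (difference -2.21 ± 0.47, adjusted p = 0.00146), as did Por (-0.995 ± 0.34, adjusted p = 0.0306). The difference of Alas1 (-1.41 ± 0.51, adjusted p = 0.0417) rests on its main probe, as its second probe changed by 0.20 in hCAR/hPXR and 0.14 in CD-1 mice. Mki67 rose more (1.96 ± 0.45, adjusted p = 0.00277) and Glul lacked the fall seen in CD-1 mice (1.87 ± 0.35, adjusted p = 0.000569). Cyp1a2 differed by 1.12 ± 0.35 (adjusted p = 0.0189). Among genes detected on every array of both strains, the largest differences were those of Spats2l (3.91), Ly6d (3.66), Rdh16f2 (3.02), Meg3 (2.86) and Krt31 (2.85) upward, and of S100a8 (-5.66), H2-T3 (-3.40), Pax2 (-3.26), the urinary protein gene Mup6 (-3.15) and Cyp2c39 (-2.58) downward. The difference of Meg3 rests on its main probe, as its other probes, not well above background on every array, changed by 0.82 and 1.69 in hCAR/hPXR and by 0.81 and 0.32 in CD-1 mice. Blocking the slide in hCAR/hPXR mice alone gave 614 genes, and CD-1 effects still hold any slide difference. Of the genes above Spats2l (4.07), Krt31 (3.57), S100a8 (-7.35) and Cyp2c39 (-1.79) passed. Not passing (second value adjusted p) were Ly6d (2.98, 0.201), Rdh16f2 (1.99), Meg3 (1.84), H2-T3 (-1.04), Pax2 (-2.58), Mup6 (-2.79), Por (-1.0, 0.289), Alas1 (-1.44, 0.316), Cyp1a2 (0.82, 0.396), Cyp2b10 (-2.48, 0.0545), Mki67 (1.71, 0.167) and Glul (1.46, 0.118). The difference was not called for Nr1i3 (-0.58 ± 0.23, adjusted p = 0.0551) or Gadd45b (0.95 ± 0.38, adjusted p = 0.0635). Differences from CD-1 mice have no exact value for Cyp2c55, not well above background in CD-1 controls, and for Afp, not well above background on any CD-1 array.

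Between C3H and CD-1 mice the effect was larger in C3H mice for 2323 genes and smaller for 1580, of 26560 tested, and scaling to the median of detected probes turned this to 1884 and 2793. Glul differed by 5.01 ± 0.42 (adjusted p = 9.57e-09), Mki67 by 3.86 ± 0.55 (adjusted p = 3.34e-05) and Cyp1a2 by 2.11 ± 0.43 (adjusted p = 0.00164). Ly6d (8.09), Spats2l (5.03), Cyp2c66 (5.01) and Meg3 (4.82) had, with Glul, the largest differences upward among genes detected on every array. The largest downward were those of Pax2 (-5.23), S100a8 (-5.08), the acute phase genes Saa1 (-3.97) and Saa2 (-3.86), and Mup6 (-3.79). The difference of Cyp2b10 (-0.96 ± 0.57, adjusted p = 0.25) did not pass. Leaving out C3H phenobarbital animal 3 gave 2472 differing genes in place of 3903.

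Between C3H and hCAR/hPXR mice the effect, with its sign, was more positive in C3H mice for 852 genes and more negative for 1155, of 20565 tested. The direction turned to 512 and 316 with quantile normalization, 895 and 707 with normexp on median signals and quantile normalization, and 225 and 71 with the slide as a block. Glul differed by 3.14 ± 0.38 (adjusted p = 2.77e-06, blocked 3.55), Nkd1 by 4.77 ± 0.38 (blocked 4.50), Mki67 by 1.90 ± 0.49 (adjusted p = 0.0139, blocked 2.16, not passing) and Afp by 2.87 ± 0.59 (adjusted p = 0.00233, blocked 2.95, not passing). Bpifa5 (5.03, blocked 4.07), Duox1 (4.82, blocked 3.52), Nxpe2 (4.77, blocked 4.73) and Calml4 (4.61, blocked 5.34) completed the largest upward differences among genes detected on every array. Downward they were Cyp3a44 (-3.82, blocked -2.57), the urea cycle gene Cps1 (-3.79, blocked -3.58), Hsd17b6 (-3.73, blocked -3.19), Hamp2 (-3.70, blocked -3.52) and Gldc, of the glycine cleavage system (-3.69, blocked -3.61), of which Gldc passed with the block. The differences of Cyp2b10 (1.25 ± 0.51, adjusted p = 0.120), Por (1.13 ± 0.37, adjusted p = 0.0506) and Ccnd1 (1.83 ± 0.62, adjusted p = 0.0605) did not pass. The count of 2007 became 296 with the slide as a block, 1096 without C3H control animal 3, and 1148 without C3H phenobarbital animal 2 or 3.

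Of 15287 genes tested in each strain, 57 rose in all 3, where independent lists would share 2.98, and 97 fell, where 24.2 would be shared. Cyp2b10, Cyp2b9, Cyp2c55, Cyp2c65, Cyp2b13, Cyp2a4, Por, Gsta1, Gstm2, Gstm3, Akr1b7, Abcc4, Prom1, Meig1, Cdc20, Birc5, Gadd45b and Orm3 were among the 42 risen genes with a symbol. Prom1 and Birc5 rest on main CD-1 probes. Slco1a1 (-1.71, -3.10 and -2.09 in CD-1, hCAR/hPXR and C3H mice), Cyp7b1, Olfr1316 and Vmn1r173 were among the 42 fallen genes with a symbol. With the slide as a block for hCAR/hPXR mice 40 genes were shared, 35 risen and 5 fallen, and the hCAR/hPXR calls of Slco1a1 (-1.51), Cyp7b1 (-1.55), Cyp2b13 (2.3, blocked 2.16) and Orm3 (2.02, blocked 0.74) were lost. Risen and fallen genes were 84 and 68 with quantile normalization, 46 and 41 with the replicate number as a block, and 35 and 9 without a filter on dim probes. Without CD-1 control animal 3 or phenobarbital animal 2 the count of 154 became 93 or 91. Without C3H control animals 1, 2 or 3 it became 54, 76 or 55, and without C3H phenobarbital animals 1, 2 or 3 it became 278, 59 or 81, and risen genes outnumbered fallen ones in these 6 cases except without phenobarbital animal 1. Across these genes, which are not independent replicates, the log2 changes correlated by Pearson 0.49 and Spearman 0.48 between hCAR/hPXR and C3H mice. The values were 0.24 and 0.17 between CD-1 and C3H mice, and 0.23 and 0.15 between CD-1 and hCAR/hPXR mice.

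The mouse receptor genes were compared between control animals to check the strain labels. Nr1i2 was well above background on 1 of 7 hCAR/hPXR control arrays and, with lower values raised to the lowest one well above background on the array, was at least 25.4-fold lower there than in CD-1 controls and at least 95.4-fold lower than in C3H controls. Nr1i3 was 6.27-fold and 18.5-fold lower on its main probe, and at least 77.3-fold and 348-fold lower on its second probe. Every hCAR/hPXR control lay below every CD-1 and C3H control for each probe, with exact two-sided permutation p = 0.00303 against CD-1 mice and p = 0.00833 against C3H mice, the smallest that 330 and 120 splits can give (Benjamini-Hochberg adjusted over the 6 tests, 0.00606 and 0.00833). Strain and array batch were not separated in this comparison.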

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

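The tests of the slopes of phenobarbital animal 1, of probes close to background and of RNA from other cell types, and the exchanges of animals between groups, were chosen only after the result was seen.

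Cyp2b10 and the sulfotransferases rose in hCAR/hPXR mice amid 11158 called genes of 20039 tested (55.7%), while treated animals 2 to 7 lay on another slide than the controls. For rises of at least 2-fold, phenobarbital animal 1, on the controls' slide, had a slope of 0.809 on the other treated animals, just below their own 0.821 to 1.03, with 98.2% of genes on the same side, so rises of similar size were measured within the controls' slide. For falls of at least 2-fold its slope was 0.311 (others 0.868 to 1.03), and for changes under 2-fold 0.394 (others 0.820 to 1.01), so a difference between slides may account for part of these changes. A weaker response of this 1 animal cannot be told apart from a difference between slides, since it is the only treated animal on its slide.

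In CD-1 mice Glul and Alb fell, and lower calls (1462) outnumbered higher calls (439). Among tested CD-1 genes above the median mean signal 19.6% of calls were higher (all genes, median -0.14), against 25.3% among the others (0.10). This argues against dim probes, not a shift with brightness. A difference between slides, not separable from phenobarbital, stays open. The genes lower in CD-1 mice had a median of -0.40 in C3H mice (quartiles -0.75 to -0.05, 77.6% lower) and -0.42 in hCAR/hPXR mice, smaller than in CD-1 mice.

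In C3H mice the pericentral genes Glul, Nkd1 and Rhbg rose together with the cell cycle genes Mki67 and Cdc20. RNA from other cell types stays open. Of 8 lists of such types 0 had a median above 0.5, but 4 had an upper quartile above it (lymphocytes 0.65, neutrophils 1.47, stellate cells 1.22, exocrine pancreas 2.22), with members going both ways. Wnt/beta-catenin activity in the sampled liver, as in tumours with an active beta-catenin, is a candidate explanation that stays open: 13 tested Wnt targets outside the fixed lists had a median of 0.12 (quartiles -0.79 to 1.73), with Myc (2.80), Apcdd1 (3.22) and Tnfrsf19 (3.75) higher and Ephb2 (-1.09) lower. Whether the samples were tumours is not stated in the labels and was not tested.

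In 32 of 224 gene groups 1 animal lay far from the others, by its gap to the nearest animal over the group's range, where chance marks about 1 in 20 groups. In hCAR/hPXR control animal 1 this held for Cyp2c55 (0.764), Cyp1a2 (0.636), Meig1 (0.725), Hsd3b5 (0.845) and Slco1a1 (0.735), all lowest, and for Prom1 (0.757), Akr1b7 (0.582), Ly6d (0.671), Lcn2 (0.595) and Apcs (0.574), all highest. In hCAR/hPXR phenobarbital animal 1 it held for Cyp2b10 (0.574), Glul (0.71), Duox1 (0.773), Vmn1r48 (0.736) and Serpina3h (0.589), and in phenobarbital animal 2 for Alas1 (0.573) and Meig1 (0.615). Other hCAR/hPXR values were Epp13 in control animal 2 (0.639), Ghrl in control animal 3 (0.826), Krt31 in control animal 4 (0.778), Gstt3 in control animal 6 (0.606), Vmn1r48 in control animal 7 (0.779) and Nudt7 in phenobarbital animal 4 (0.731). In CD-1 mice they were Cyp2b13 (0.897), Birc5 (0.992) and Mki67 (0.853) in control animal 1, Gsta1 (0.852), G6pc (0.863), Etnppl (0.922) and Nr1i3 (0.838) in phenobarbital animal 1, Abcc4 (0.864) in phenobarbital animal 2 and Olfr1316 (0.864) in phenobarbital animal 4. Groups of 3 animals were not examined.

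The effect of phenobarbital differed between strains, by a test of the difference itself, for 7524 genes between hCAR/hPXR and CD-1 mice, 3903 between C3H and CD-1 mice and 2007 between C3H and hCAR/hPXR mice. Between hCAR/hPXR and CD-1 mice the named differences were Spats2l 3.91, Ly6d 3.66, Rdh16f2 3.02, Meg3 2.86, Krt31 2.85, Mki67 1.96, Glul 1.87, Cyp1a2 1.12, S100a8 -5.66, H2-T3 -3.40, Pax2 -3.26, Mup6 -3.15, Cyp2c55 -2.73, Cyp2c39 -2.58, Cyp2b10 -2.21, Alas1 -1.41 and Por -0.995. Of these, Spats2l, Krt31, S100a8, Cyp2c39 and Cyp2c55 passed with hCAR/hPXR slides blocked and others did not, some at values nearly as large (Por -1.0, Alas1 -1.44, Mup6 -2.79). Other probes did not all match Alas1 and Meg3. Between C3H and CD-1 mice they were Ly6d 8.09, Spats2l 5.03, Cyp2c66 5.01, Glul 5.01, Meg3 4.82, Afp 3.95, Mki67 3.86, Cyp1a2 2.11, Pax2 -5.23, S100a8 -5.08, Saa1 -3.97, Saa2 -3.86, Mup6 -3.79 and Cyp2c55 -1.59. The fitted values against CD-1 mice are not measured differences for Afp, not well above background on any CD-1 array, and for Cyp2c55, not well above background in CD-1 controls. Between C3H and hCAR/hPXR mice they were Bpifa5 5.03, Duox1 4.82, Nkd1 4.77, Nxpe2 4.77, Calml4 4.61, Glul 3.14, Afp 2.87, Mki67 1.90, Cyp3a44 -3.82, Cps1 -3.79, Hsd17b6 -3.73, Hamp2 -3.70 and Gldc -3.69, and the slide block, with wider errors, ended the calls of Afp (2.95), Mki67 (2.16), Cyp3a44 (-2.57), Cps1 (-3.58), Hsd17b6 (-3.19) and Hamp2 (-3.52). Strain, dose, duration, carcinogen and batch were not separated.

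Other splits exclude chance in CD-1 mice, for slide and treatment jointly. The real 1 of 35 gave 1901 genes, 1833 changed at least 2-fold (highest other 0 each). It gave 16 lists against up to 13 in others, which backs no single list. In hCAR/hPXR mice 1 of 100 gave as many as 11158 genes (highest other 8220) and 2002 changed at least 2-fold (highest other 1303). This speaks against chance for slide and treatment only jointly. For lists 4 of 100, 3 of them other splits, gave as many as 15 (highest other 17). The split with 8220 genes exchanged phenobarbital animal 1 for a control and so follows the slides, and the slide-blocked count is 438. Exchanging phenobarbital animal 1 for each control gave 7231 to 9801 genes (median 8838), and exchanging any of animals 2 to 7 gave 0 to 5477 (limma, median 0). The median was 1997 for animal 5, and exchanges of animals 2 to 6 for control animal 7 gave 2830 to 5477, so large counts did not come from phenobarbital animal 1 alone. In C3H mice 10 splits are too few for a share under 0.05: 1 of 10 gave as many as 2913 genes (highest other 0), as many as 1448 changed at least 2-fold (highest other 0) and as many as 17 lists (highest other 14).

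For the differences 1 of 100 splits gave as many as 7524 genes between hCAR/hPXR and CD-1 mice (highest other 3785). C3H against CD-1 mice reached 3903 in 1 (highest other 1551), and C3H against hCAR/hPXR mice 2007 in 3 (highest others 6151 and 2322). These splits test for no effect, so cannot decide whether effects differ. The splits with 6151 and 2322 genes kept the C3H groups and exchanged 7 and 5 of the 7 hCAR/hPXR phenobarbital animals for controls, so effects largely added up. The slide-blocked count is 296. For the 154 genes changed alike in all 3 strains 1 of 100 splits gave as many (highest other 0).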

How the results depend on the processing

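The alternatives with normexp on median signals followed by quantile normalization, the arrays of 1 slide, detection on all 28 arrays, genes with a symbol, slide-blocked lists and leave-one-out for named genes were tests chosen only after the result was seen. The rises of Cyp2b10, Cyp2c55, Por and Gadd45b kept their direction and their side of the threshold in each strain under every alternative run for the whole comparison, except that the arrays of 1 slide ended the call for Por in hCAR/hPXR mice, and leaving out control animal 3 or phenobarbital animal 2 ended that for Gadd45b in C3H mice (2.87, adjusted p = 0.0653, and 3.01, adjusted p = 0.0554). Over all named genes, 3650 values had the same direction and side of the threshold, 445 fell short of it, 10 newly passed and 14 reversed. For differences the numbers were 802, 34, 35 and 2, and for lists 604, 92, 13 and 4. Of all 5705 values, 60 past the threshold in neither setting changed sign. Where no reason is given below, the cause was not tested.

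With normexp and quantile normalization the counts were 3801 genes in CD-1 mice, 465 and 624 changed at least 2-fold in hCAR/hPXR and C3H mice, 242 in all 3 strains and 7643 for C3H against CD-1 mice. Quantile normalization gave 828 for C3H against hCAR/hPXR mice and 10 lists in CD-1 mice. Scaling to the median of detected probes moved the median of all genes by over 0.1, to -0.26 and -0.31, and the share of upward differences from 65.2% to 36.8% for hCAR/hPXR against CD-1 mice and from 59.5% to 40.3% for C3H against CD-1 mice. Without a filter on dim probes, when more genes are tested, C3H mice had 625 (619 at least 2-fold) and all 3 strains 44. Detection in both groups, which leaves fewer genes, gave 1314 changed at least 2-fold in hCAR/hPXR mice and 2061 for C3H against CD-1 mice. All 6 groups in 1 fit, which pools the spread over the strains, gave 6216 (2875) in CD-1 mice, 7795 in hCAR/hPXR mice and 243 in all 3 strains. Array weights gave 4197 in CD-1 mice, 5937 (2326) in C3H mice, 455 in all 3 strains and 7464 for C3H against hCAR/hPXR mice. Detection on all 28 arrays, with fewer genes, gave 1049, 933 and 714 changed at least 2-fold in CD-1, hCAR/hPXR and C3H mice, and 2003 and 1320 for C3H against CD-1 and hCAR/hPXR mice. Genes with a symbol were 911 (881) in CD-1, 6904 (855) in hCAR/hPXR and 1882 in C3H mice. Testing every probe gave 238 in all 3 strains, Dnajb11 -1.01 in hCAR/hPXR mice, and for hCAR/hPXR against CD-1 mice Nr1i3 1.60 and Cyp3a11 0.88, through other probes of these genes. The mean of probes gave Dnajb11 -0.31.

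The replicate number as a block gave 1120 (1120) in CD-1 mice, 1712 in C3H mice, 87 in all 3 strains and 1333 for C3H against hCAR/hPXR mice. Deviations of animals of the same number correlated by -0.45 to 0.06 in CD-1 mice, -0.13 to 0.27 in hCAR/hPXR mice and 0.04 to 0.18 in C3H mice, where each animal matched its own number best but not all values passed 0.1, so pairing was not assumed. The slide as a block gave 438 (293) in hCAR/hPXR mice, 40 in all 3 strains, 614 for hCAR/hPXR against CD-1 mice and 296 for C3H against hCAR/hPXR mice, and the arrays of 1 slide 251 (214), with fewer samples. With the slide block and on 1 slide, Slc27a5 was -0.22, Fgb -0.12, Hpx -0.0327, C1qb -0.0548, Cd5l -0.24 and Hbb-b2 0.0293, and the medians of acute phase proteins and Kupffer cells were -0.13 and -0.0306. The slide block could not be fitted for CD-1 mice or C3H against CD-1 mice, and C3H mice had 1 slide. Normexp on mean signals was not run, since the files hold no such values.

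With an estimated correlation camera called 1, 0 and 0 lists in CD-1, hCAR/hPXR and C3H mice, against 16, 15 and 17. Fry called 3, 17 and 15 (3, 14 and 13 shared). Leave-one-out ranges were 910 to 2046 in CD-1 mice (910 to 2040 at least 2-fold), 622 to 5547 in C3H mice (570 to 2660), 54 to 278 in all 3 strains, 2472 to 5037 for C3H against CD-1 mice, 1096 to 2703 for C3H against hCAR/hPXR mice and, within 1.5 times, 10380 to 11718 in hCAR/hPXR mice and 6104 to 8856 for hCAR/hPXR against CD-1 mice. The number of arrays limits the precision.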

Other observations

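The gene lists were fixed before the data were examined, and the slide-blocked list medians of hCAR/hPXR mice were tests chosen only after the result was seen. Counts of called members were the same when adjusted over the list alone unless other counts follow, and the second of 2 adjusted p of a list is with an estimated correlation. In CD-1 mice Srebf1, of fatty acid synthesis, Cyp7b1 and Hsd3b7, of bile acid synthesis, and Bmp2, of the endothelium, fell. Values in brackets are log2 changes of called members among the 4 with the smallest adjusted p, and groups overlapped for Hsd3b7 alone among those of CD-1 mice. Of 22 genes of cholesterol synthesis and uptake limma called 0, with 5 at unadjusted p under 0.05 (median -0.29, adjusted p = 0.154). Of 18 fatty acid synthesis genes 1 fell (Srebf1 -1.12), and 1 rose and 8 fell when adjusted over the list alone (median -0.71, adjusted p = 0.0343 and 0.763). Of 12 bile acid synthesis genes 2 fell (Cyp7b1 -1.46, Hsd3b7 -1.24), and 1 rose and 6 fell when adjusted over the list alone (median -0.79, adjusted p = 0.0119 and 0.637). Of 17 NRF2 targets limma called 0, with 3 at unadjusted p under 0.05 (median 0.06, adjusted p = 0.926). Of 9 p53 targets 1 rose (Gdf15 1.86) (median 0.05, adjusted p = 0.802). Of 15 ER stress and ATF4 targets limma called 0, with 2 at unadjusted p under 0.05 (median -0.27, adjusted p = 0.802). Of 12 interferon-stimulated genes limma called 0, with 2 at unadjusted p under 0.05 (median 0.60, adjusted p = 0.00779 and 0.612). Of 12 circadian clock genes 1 fell (Hlf -1.15), and 2 fell when adjusted over the list alone (median -0.18, adjusted p = 0.334).

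Cel, Cldn4, Cd79a and Dusp1, each from a different tissue programme, fell in CD-1 mice. Of 10 immediate-early and heat-shock genes 1 fell (Dusp1, not well above background on any phenobarbital array), and 1 rose and 1 fell when adjusted over the list alone (median -0.07, adjusted p = 0.802). Of 12 genes of Kupffer cells and macrophages limma called 0, with 2 at unadjusted p under 0.05 (median -0.01, adjusted p = 0.983). Of 10 lymphocyte genes 1 fell (Cd79a -1.66) (median 0.05, adjusted p = 0.802). Of 13 endothelial genes 1 fell (Bmp2 -1.23), and 6 fell when adjusted over the list alone (median -0.70, adjusted p = 0.0140 and 0.612). Of 12 genes of stellate cells and fibroblasts 2 fell (Ecm1 -1.10, Acta2 -1.19), and 4 fell when adjusted over the list alone (median -0.44, adjusted p = 0.109). Of 8 bile duct genes 1 fell (Cldn4 -1.89) (median 0.00, adjusted p = 0.740). Of 5 red blood cell genes limma called 0, with 1 at unadjusted p under 0.05, and 1 fell when adjusted over the list alone (median -0.16, adjusted p = 0.802). Of 6 genes of the exocrine pancreas 1 fell (Cel -1.15) (median -0.10, adjusted p = 0.542).

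In hCAR/hPXR mice Elovl6 and Fads1, which lengthen and desaturate fatty acids, and Irgm1, an interferon-induced GTPase, rose, and Elovl6 passed with the slide as a block. Blocked values stand after a slash. With the block limma called 0 members of the lists in this paragraph apart from Elovl6 and Acadl (-0.27/-1.09), of fatty acid oxidation. At unadjusted p under 0.05 there were 6 genes each of fatty acid synthesis and oxidation, 5 each of gluconeogenesis and the periportal list, 4 immediate-early, 3 interferon-stimulated, 2 bile acid, 1 ER stress and 0 clock genes. Mlxipl, Ifit2 and Atf3 were well above background on 6 of 7 control arrays and Cry1 on 3 of 7 phenobarbital arrays. Groups did not overlap for Fads1, Elovl6, Mlxipl, Agxt, Herpud1, Irgm1, Klf6, Serpinc1, Cd4, Nkg7, Cd3e, Kdr and Egfl7, and overlapped for the other members given for hCAR/hPXR mice. Of 12 bile acid synthesis genes 2 rose and 2 fell (Akr1d1 0.73/0.84, Cyp7b1 -0.99/-1.55, Baat -0.74/-0.14, Slc27a5 0.21/-0.22), and 1 rose and 2 fell when adjusted over the list alone (median 0.19, blocked 0.00, adjusted p = 0.706). Of 18 fatty acid synthesis genes 10 rose (Fads1 0.61/0.45, Elovl6 1.23/1.61, Mlxipl 0.61/0.41, Acaca 0.53/0.56) (median 0.38, blocked 0.38, adjusted p = 0.0443 and 0.776). Of 21 genes of fatty acid oxidation and PPARA targets 2 rose and 2 fell (among them Pdk4 0.77/0.84, Vnn1 0.83/1.07, Angptl4 -0.76/-1.75), and 2 rose and 1 fell when adjusted over the list alone (median 0.04, blocked 0.13, adjusted p = 0.901). Of 14 genes of gluconeogenesis and amino acid breakdown 1 rose and 3 fell (Agxt 0.68/0.23, Ppargc1a -0.64/-0.69, Got1 -0.51/-0.92, Tdo2 -0.40/-0.26) (median -0.11, blocked -0.38, adjusted p = 0.637, blocked adjusted p = 0.00461). Of 15 periportal genes 2 rose and 2 fell (Ctsc 1.07/0.28, Etnppl -1.09/-0.42, Sox9 0.45/0.50, Cdh1 -0.35/-0.35), and 1 rose and 1 fell when adjusted over the list alone (median -0.07, blocked -0.35, adjusted p = 0.712, blocked adjusted p = 0.0208). Of 16 ER stress and ATF4 targets 4 rose and 1 fell (Herpud1 -1.18/-0.77, Pdia4 0.66/0.29, Dnajb11 0.39/0.05, Hsp90b1 0.52/0.21), and 1 rose and 1 fell when adjusted over the list alone (median 0.28, blocked 0.15, adjusted p = 0.423). Of 18 interferon-stimulated genes 11 rose (Irgm1 0.80/0.62, Ifit2 0.75/0.73, Isg15 0.91/0.91, Igtp 0.72/0.82) (median 0.55, blocked 0.70, adjusted p = 0.0131 and 0.776). Of 13 circadian clock genes 1 rose and 2 fell (among them Cry1 -1.09/-0.11, Per1 -0.75/-0.95) (median 0.04, blocked 0.10, adjusted p = 0.637). Of 13 immediate-early and heat-shock genes 4 rose and 2 fell (Klf6 0.65/0.42, Atf3 0.81/0.95, Hsph1 0.70/0.80, Dusp1 -0.94/-0.91) (median 0.13, blocked -0.77, adjusted p = 0.773).

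Cd4 and Cd3e, of T cells, and Kdr, a receptor of endothelial cells (second probe -0.07), fell in hCAR/hPXR mice, calls lost with the slide as a block. With the block limma called 0 members of the lists in this paragraph, with 3 endothelial, 2 lymphocyte, 2 secreted protein and 0 other genes at unadjusted p under 0.05. Of 14 hepatocyte secreted proteins 2 rose and 1 fell (Fgb 0.55/-0.12, Hpx 0.40/-0.03, Serpinc1 -0.16/-0.12) (median -0.05, blocked -0.24, adjusted p = 0.807, blocked adjusted p = 0.000870). Of 14 genes of Kupffer cells and macrophages 6 rose (C1qa 0.62/0.02, Mpeg1 0.65/0.28, C1qb 0.47/-0.05, Cd5l 0.59/-0.24) (median 0.37, blocked -0.03, adjusted p = 0.0421 and 0.776, blocked adjusted p = 0.755). Of 12 lymphocyte genes 4 rose and 3 fell (Cd4 -1.45/-0.83, Nkg7 -0.53/-0.35, Cd3e -0.93/-0.45, Ltb 0.48/0.30) (median 0.10, blocked -0.19, adjusted p = 0.779). Of 5 neutrophil genes 1 fell (Camp -0.55/-0.46) (median 0.77, blocked -0.47, adjusted p = 0.807). Of 14 endothelial genes 6 rose and 1 fell (Kdr -1.23/-0.86, Lyve1 0.85/0.85, Egfl7 0.43/0.29, Gpihbp1 0.38/0.04) (median 0.20, blocked 0.03, adjusted p = 0.423). Of 13 genes of stellate cells and fibroblasts 3 rose and 1 fell (Col3a1 0.79/0.76, Lrat -0.35/-0.23, Acta2 0.74/0.16, Colec11 0.49/0.29) (median 0.20, blocked 0.02, adjusted p = 0.712). Of 7 bile duct genes 2 rose and 1 fell (Cftr -1.21/-0.07, Krt19 0.87/0.49, Sox9 0.45/0.50) (median -0.01, blocked 0.00, adjusted p = 0.881). Of 7 red blood cell genes 3 fell (among them Hbb-b2 -0.62/0.03, Alas2 -0.51/-0.09), and 1 fell when adjusted over the list alone (median -0.26, blocked 0.00, adjusted p = 0.199). Of 5 genes of the exocrine pancreas 3 fell (Clps -1.27/-0.32, Ctrb1 -0.66/-0.23, Cel -0.76/-0.10) (median -0.66, blocked -0.10, adjusted p = 0.216).

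In C3H mice Vnn1, Cidec and Acot2, targets of PPARA, rose, and the fibrinogen genes Fga and Fgb fell while Orm3 rose. Vnn1 and Acot2 were well above background on 1 and Ifit2 on 2 of 3 control arrays. Of 23 genes of cholesterol synthesis and uptake limma called 0, with 3 at unadjusted p under 0.05 (median 0.25, adjusted p = 0.0385 and 0.689). Of 17 fatty acid synthesis genes 1 rose and 3 fell (Acss2 -0.67, Acacb -0.93, Pklr 0.63, Srebf1 -0.77) (median -0.17, adjusted p = 0.889). Of 22 genes of fatty acid oxidation and PPARA targets 3 rose and 1 fell (among them Vnn1 2.78, Cidec 2.26, Acot2 2.07), and 4 rose and 1 fell when adjusted over the list alone (median 0.33, adjusted p = 0.0824). Of 16 ER stress and ATF4 targets 3 rose and 3 fell (Ddit3 2.41, Trib3 1.96, Sdf2l1 -0.66, Chac1 1.57), and 3 rose and 4 fell when adjusted over the list alone (median -0.11, adjusted p = 0.889). Of 20 acute phase proteins 1 rose and 5 fell (Orm3 2.64, Itih3 -0.89, Fga -1.40, Fgb -1.03), and 2 rose and 6 fell when adjusted over the list alone (median -0.36, adjusted p = 0.0731). Of 17 interferon-stimulated genes 4 rose (Usp18 1.98, Oas1a 0.86, Ifit2 0.95, Ifit1 0.73), and 5 rose when adjusted over the list alone (median 0.58, adjusted p = 0.000367 and 0.474). Of 12 circadian clock genes 1 fell (Nfil3 -1.55) (median 0.59, adjusted p = 0.612). Of 14 genes of Kupffer cells and macrophages 1 fell (Folr2 -0.96), and limma called 0 when adjusted over the list alone (median -0.24, adjusted p = 0.201).

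Cela1 and Cela3b, elastases of the pancreas, and Krt19, a keratin of bile ducts, rose in C3H mice. Of 9 lymphocyte genes 1 rose (Gzma 0.65), and 1 rose and 2 fell when adjusted over the list alone (median 0.23, adjusted p = 0.719). Of 4 neutrophil genes 1 fell (Csf3r -0.47) (median 0.48, adjusted p = 0.974). Of 14 endothelial genes 1 rose and 4 fell (Kdr -0.69, Dnase1l3 -0.75, Bmp2 -0.89, Lyve1 1.29), and 1 rose and 5 fell when adjusted over the list alone (median -0.30, adjusted p = 0.249). Of 12 genes of stellate cells and fibroblasts limma called 0, with 7 at unadjusted p under 0.05 (median -0.18, adjusted p = 0.720). Of 7 bile duct genes 1 rose and 1 fell (Sox9 at least 4.56-fold, Krt19 2.85), and 1 rose and 3 fell when adjusted over the list alone (median -1.65, adjusted p = 0.330). Of 7 red blood cell genes limma called 0, with 2 at unadjusted p under 0.05 (median -0.45, adjusted p = 0.148). Of 6 genes of the exocrine pancreas 2 rose and 1 fell (Cela1 4.27, Ctrb1 -0.81, Cela3b at least 3.95-fold), and 2 rose and 2 fell when adjusted over the list alone (median -0.16, adjusted p = 0.847).

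The median, the mean and the test of a list differed in sign for NRF2 targets in CD-1 mice (mean -0.05), in hCAR/hPXR mice for PPARA targets (-0.02), clock genes (-0.10), secreted proteins (0.05), lymphocytes (-0.05), neutrophils (0.43) and bile duct genes (0.09), and in C3H mice for fatty acid synthesis (-0.01), ER stress and ATF4 targets (0.15), stellate cells (0.14) and the exocrine pancreas (0.85). None of these lists was called in the main fit. Secreted proteins, gluconeogenesis and periportal genes of hCAR/hPXR mice were called lower with the slide as a block and on 1 slide.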
